A study of Cavia porcellus with 10 samples.

How the data were processed

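RNA-seq libraries were made from the sclera of 10 eyes of male guinea pigs (Cavia porcellus), 5 with lens-induced myopia and 5 untreated. The labels name an mRNA library kit of the SMARTer family for total RNA. The values are raw counts of reads per gene symbol, deposited as a table with 1 column per library; they are whole numbers that sum to between 32309258 and 35430797 per library. The aligner, the counter, the annotation and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The submitters' processing notes name the genome builds GRCm38 and mm10, which are mouse builds, without saying what they were used for, and the gene symbols are of mixed case. For that reason no coordinate or gene length is given, and a guinea pig gene table (assembly mCavPor4.1) served only to look up names, of which 91.1% of the 16421 distinct symbols were found.

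Columns were assigned to groups by the library names in the labels. Control and myopia libraries both carry the numbers 1 to 5, and since lenses were worn on both eyes, animals of the groups differ. The labels do not say which eyes share an animal, so p-values measure the spread between these samples, which may be smaller than that between animals. No label names a batch. Pairs of replicates differed by more than counting noise (chi-square per degree of freedom from 18.2 to 120), so no library was taken for a copy of another.

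Of 18079 lines of the table, 437 carry no symbol. They held 1.18% to 1.69% of the counts in control and 0.751% to 0.824% in myopia, and were left out of library sizes and tests. The remaining 17642 lines hold 723 symbols on more than 1 line (1944 lines, ignoring case). Each line was tested as its own gene; the line with the highest mean kept the plain symbol, and others are called the second entry. With filterByExpr in edgeR (minimum count 10, minimum total 15), 14683 genes were kept and 2959 were not tested.

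Differences between groups were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, glmQLFit with robust dispersion, glmQLFTest, 1 factor for group) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. TMM factors were 0.777 to 0.968 in control and 1.11 to 1.25 in myopia. The biological coefficient of variation was 0.204. Standard errors of log2 fold changes are the fold change divided by the square root of the quasi-likelihood F statistic, and CPM values are scaled with the TMM factors. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with adjustment over the 37 of 38 lists that had at least 5 measured members; 23 genes stand in more than 1 list. Each list was also tested with an estimated correlation, under which 0 lists passed (8 with the preset correlation, 16 with fry, which tests whether a list moves on balance and does not compare it with other genes). The lists cover collagens, other matrix genes, matrix enzymes, signalling pathways, metabolism, immune genes, ribosomal proteins, and markers of tissues that a dissection of sclera can carry along; each list's result is in the report. Within each list, counts of genes past the test are given over all genes and, where they differ, adjusted over the list alone.

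The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 10 genes with the highest and the 10 with the lowest log2 fold change among those with an adjusted p under 0.05, a mean of at least 2 CPM and no overlap between the groups; from each list described gene by gene, at most 4 members past the threshold, by smallest p; and COL1A1, COL1A2, COL3A1, MMP2, TIMP2, TGFB1, TGFB2, HIF1A, ACTA2, LOX and DCN in any case. The other lists are given as counts. Some ribosomal protein genes that the rule selects are left out of the text on request, after the results were seen. Alternatives were other scaling factors (RLE, upper quartile, total count), other filters, DESeq2 1.42.0, limma-voom with and without sample quality weights, dispersion without robust estimation, a replicate block, 1 surrogate variable from sva 3.50.0, and leaving out each library in turn. Lines of a symbol summed, and control libraries 4 and 5 left out, were added after the data were seen, as were further lists described as such.

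The gene test was tested on simulated data, drawn for the same 14683 genes from their means, dispersions and library sizes with 200 genes changed by known folds. It recovered 75.5% of the 2-fold and 98.0% of the 4-fold changed genes, called 11 unchanged genes and no gene in the wrong direction (0 calls). The list test called a simulated list shifted by 0.7 on the log2 scale and 0 of the unshifted lists. Simulated genes were drawn independently of one another, and few were changed. The simulation therefore did not check lists whose members vary together, nor the scaling when most genes differ. At these totals the spread between libraries limits the precision for all but genes with low counts. Summed counts are given for ZBTB41 and Syt8 only. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.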

Results

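The data were RNA-seq counts of whole scleral tissue, the collagen-rich outer coat of the eye, from male guinea pigs aged 2 to 3 weeks. In the treated group both eyes wore lenses that make the eye nearsighted (lens-induced myopia), and control animals were untreated. Each group had 5 libraries, each from 1 eye. The total count per library lay between 32309258 and 35430797, with means of 34238000 in control (SD 1280000) and 33040000 in myopia (SD 698500). The comparison asked which transcripts of the sclera differed between myopic and untreated eyes.

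In the myopic sclera, COL1A1, Col3a1 and the elastin gene were lower than in control, as were most genes of the ribosome, the mitochondrial respiratory chain and the interferon response. COL1A1, the main collagen chain of the sclera, fell from 82728 ± 9358 CPM in control to 35555 ± 3273 CPM in myopia (mean ± SD, n = 5 per group), a log2 fold change of -1.22 ± 0.15 (SE). HIF1A, the oxygen-regulated transcription factor, rose from 50.2 ± 13.2 to 119.8 ± 10.9 CPM, a log2 fold change of 1.25 ± 0.15. Lox, a collagen cross-linking enzyme, rose from 21.8 ± 11.7 to 74.4 ± 8.27 CPM, and Tgfb2, a growth factor of the scleral matrix, from 47.5 ± 16.8 to 113.0 ± 8.65 CPM. With the main axis of the control libraries projected out of the difference in mean log2 CPM, a step chosen after the data were seen, these rises shrank, from 1.29 to 0.37 for HIF1A, from 1.92 to 0.02 for Lox and from 1.31 to 0.17 for Tgfb2, and COL1A1 went from -1.22 to -0.89. That axis held 52.3% of the squared difference between the groups, so the step also takes out any response to the lenses along it. The myopia libraries scored 91.4 to 104 on it, beyond the control libraries at -39.4 to 55. The values left are therefore not corrected effects. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 10561 of 14683 genes passed an adjusted p of 0.05, 5412 of them higher and 5149 lower in myopia. With an absolute log2 fold change of at least 1 as a second condition, 2872 were higher and 1845 lower. The 5 myopia libraries all lay on one side of the 5 control libraries for 8491 of the genes tested (57.8%), where chance gives 0.794%. When libraries were scaled by total count alone the median log2 fold change of the genes tested moved from 0.03 to 0.48. Of 10384 calls 73.5% were then higher, against 51.2% with TMM factors, so higher and lower here are relative to the TMM scale.

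The libraries differed along a single main direction that also spread the untreated libraries. The first principal component of log2 CPM held 77.1% of the variance. On it the control libraries 1 to 5 scored -94.6, -87.4, -81.5, -49.7 and -24.6, and the myopia libraries scored from 61.5 to 72.5. Control libraries 4 and 5 thus lay nearest to the myopia libraries. The control libraries followed the order of their numbers on this component, in TMM factors (0.777 to 0.968) and in genes detected (15706 to 15982). The myopia libraries did not, and the labels do not say what the numbers follow. Ribosomal protein genes held 10.1%, 10.4%, 9.02%, 7.85% and 7.24% of the counts in control libraries 1 to 5, and 4.70 ± 0.24% in myopia (mean ± SD, n = 5). COL1A1 alone held 7.05 ± 0.458% of the counts in control and 4.15 ± 0.237% in myopia. Among the 5 control libraries alone, the gene weights of the first principal component correlated with the fold change between the groups at a Spearman rho of 0.73 across 14683 genes, which are not independent replicates. Without control libraries 4 and 5, an alternative chosen after the data were seen, 10919 genes passed.

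**Figure D1:**
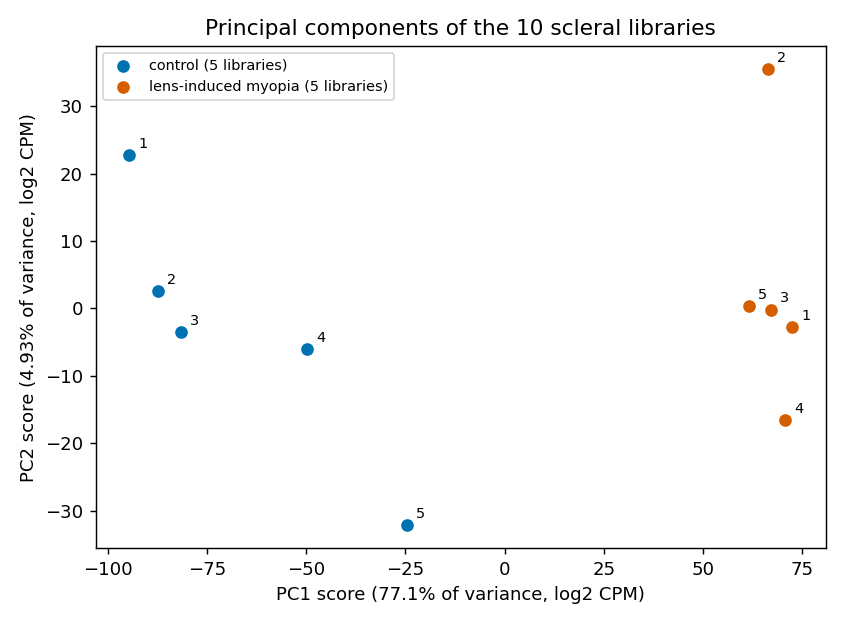
Scores of the 10 libraries on the first (x axis, 77.1% of variance) and second (y axis, 4.93% of variance) principal components of log2 CPM. Points are libraries, coloured by group and labelled with their replicate number, and the control libraries span -94.6 to -24.6 on the first component while the myopia libraries lie between 61.5 and 72.5.

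Among the fibrillar collagens, 4 of 11 measured genes rose, 4 fell and 3 did not pass. COL1A1 fell (adjusted p = 8.04e-06) and Col3a1 fell by 0.91 ± 0.13 on the log2 scale (SE; adjusted p = 3.75e-05). The minor fibrillar collagens COL24A1, COL27A1 and COL11A1 rose by 1.86 ± 0.15, 1.23 ± 0.14 and 1.30 ± 0.17. COL1A2, the partner chain of COL1A1, had a log2 fold change of -0.29 ± 0.14 that did not pass (adjusted p = 0.0713) and that turned positive, to 0.15, with scaling by total count. It passed with DESeq2 (adjusted p = 0.00395), with sample quality weights (adjusted p = 0.0249), with 1 surrogate variable (adjusted p = 0.0282), and without control 5 (-0.31, adjusted p = 0.0421) or myopia 2 (-0.36, adjusted p = 0.0461). Of 24 measured fibril-associated, network and microfibrillar collagens, 10 rose and 8 fell. The basement membrane chains Col4a3 and COL4A5 rose by 2.71 ± 0.25 and 1.24 ± 0.14, while COL4A2 fell from 416 ± 75.3 to 208 ± 12.4 CPM and Col6a2 from 3058 ± 541 to 1127 ± 205 CPM (mean ± SD, n = 5). Neither collagen list passed as a list in camera (adjusted p = 0.947 for both).

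Of 32 proteoglycan and hyaluronan genes, 8 rose and 9 fell. Bgn (biglycan), a small proteoglycan of collagen fibrils, fell from 6892 ± 1544 to 2105 ± 253 CPM. KERA (keratocan), Aspn (asporin) and ECM2 rose by 1.86 ± 0.22, 1.41 ± 0.12 and 1.49 ± 0.18 on the log2 scale (SE, n = 5 per group). DCN (decorin) went from 5690 ± 270 to 7616 ± 1950 CPM, a log2 fold change of 0.42 ± 0.17 (adjusted p = 0.0377). That call did not hold with RLE factors (adjusted p = 0.0512), nor without control 3 (0.40, adjusted p = 0.0701), myopia 1 (0.44, adjusted p = 0.0549), myopia 2 (0.28, adjusted p = 0.118) or myopia 3 (0.39, adjusted p = 0.0833). The list did not pass in camera (adjusted p = 0.665).

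Of 17 measured elastic fibre and microfibril genes 10 fell, 2 rose and 5 did not pass, with a median log2 fold change of -0.90. ELN (elastin) fell from 1353 ± 114 to 504 ± 58.8 CPM, and the fibre-assembly genes Emilin2, Emilin1 and Fbln2 fell with log2 fold changes of -1.88 ± 0.12, -1.35 ± 0.10 and -1.06 ± 0.09 (SE, n = 5 per group). The list passed camera with a preset correlation of 0.01 (adjusted p = 0.00875) and did not pass with an estimated correlation (adjusted p = 0.922 with an estimated correlation). The mean of its members lay between -0.06 and 0.05 in the control libraries, relative to the control mean, and between -0.94 and -0.50 in the myopia libraries. Control libraries 4 and 5 did not stand apart for this list.

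Among collagen processing and cross-linking enzymes 17 of 28 measured members fell and 7 rose (18 and 8 adjusted over the list alone), with a median log2 fold change of -0.43. LOXL1, a lysyl oxidase of elastic fibres, ADAMTS2, the procollagen N-proteinase, P4hb, a subunit of prolyl 4-hydroxylase, and PLOD3, a lysyl hydroxylase, fell with log2 fold changes of -1.30 ± 0.09, -1.16 ± 0.12, -0.91 ± 0.10 and -0.93 ± 0.11 (SE, n = 5 per group). Lox moved the other way, with a log2 fold change of 1.77 ± 0.30 (adjusted p = 0.000174). Its control libraries 1 to 5 stood at 11.2, 12.2, 18.8, 28.2 and 38.8 CPM, and the lowest myopia library at 65.9 CPM. The list passed camera with the preset correlation (adjusted p = 0.048), but its median was 0.03 with scaling by total count, and adjusted p = 0.922 with an estimated correlation. The call also ended without control 1, control 4, myopia 1 or myopia 4, with adjusted p values of 0.0511, 0.0545, 0.0564 and 0.0836 and medians of -0.40, -0.43, -0.46 and -0.42, and without control libraries 4 and 5 together (adjusted p = 0.0654).

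Of 25 measured matrix-degrading proteases 10 fell and 7 rose, and of 12 protease inhibitors 7 fell and 2 rose. MMP2, a gelatinase, fell from 4519 ± 577 to 2699 ± 484 CPM, a log2 fold change of -0.74 ± 0.15 (adjusted p = 0.000544), and the lysosomal protease CTSB fell by 1.09 ± 0.16 on the log2 scale. The aggrecan- and versican-cleaving proteases ADAMTS5 and Adamts1 rose by 2.24 ± 0.22 and 1.62 ± 0.19, and the sheddase ADAM10 by 1.04 ± 0.11. The metalloproteinase inhibitors TIMP3, TIMP1 and TIMP4 fell with log2 fold changes of -0.95 ± 0.10, -1.35 ± 0.17 and -0.80 ± 0.14, as did the complement inhibitor Serping1, by 1.37 ± 0.16. TIMP2, at 2997 ± 185 and 2763 ± 330 CPM, had a log2 fold change of -0.12 ± 0.12 that did not pass (adjusted p = 0.385) and that became 0.33 with scaling by total count. As lists, neither proteases (adjusted p = 0.623) nor inhibitors (adjusted p = 0.202) passed camera.

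Genes of the TGF-beta and BMP pathway moved both ways, 18 of 42 measured members up and 11 down. TGFB1 fell from 64.5 ± 7.44 to 27.7 ± 2.82 CPM (log2 fold change -1.22 ± 0.10, adjusted p = 6.53e-07), and FSTL3, an activin antagonist, fell by 0.89 ± 0.08. Tgfb2 rose by 1.25 ± 0.19 (adjusted p = 7.28e-05), the receptor BMPR2 by 1.25 ± 0.12 and the signal transducer SMAD2 by 1.05 ± 0.09 on the log2 scale (SE, n = 5 per group). Tgfb2 stood at 60.2 and 70.5 CPM in control libraries 4 and 5 and at 33.6 to 39.1 CPM in control libraries 1 to 3. The list did not pass camera (adjusted p = 0.593).

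Of 24 measured hypoxia response genes 13 rose and 6 fell. HIF1A (adjusted p = 7.52e-06), its partner ARNT and PDK1, a kinase that inhibits pyruvate dehydrogenase in mitochondria, rose by 1.25 ± 0.15, 1.24 ± 0.16 and 1.03 ± 0.09 on the log2 scale, and HMOX1, which degrades haem, fell by 1.63 ± 0.18 (SE, n = 5 per group). HIF1A stood at 56.7 and 70.3 CPM in control libraries 4 and 5 and at 38.4 to 44.2 CPM in control libraries 1 to 3. The hypoxia list did not pass camera (adjusted p = 0.404). It passed fry as higher (adjusted p = 0.00195), a test that does not compare it with other genes. Glycolytic genes, many of them targets of HIF1A, fell: 14 of 22 were lower and 0 higher, with a median log2 fold change of -0.57. PKM, ENO1, Pfkl and HK1 fell with log2 fold changes of -1.08 ± 0.09, -1.18 ± 0.12, -1.24 ± 0.12 and -0.67 ± 0.08. The glycolysis list passed camera with the preset correlation (adjusted p = 0.0164; adjusted p = 0.922 with an estimated correlation).

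Nuclear-encoded genes of the mitochondrial respiratory chain fell in 37 of 43 measured cases and rose in 2 (38 and 2 adjusted over the list alone), with a median log2 fold change of -0.78. COX6A1 and COX8A, subunits of cytochrome c oxidase, fell with log2 fold changes of -1.57 ± 0.11 and -1.43 ± 0.12, and NDUFS8 and NDUFS7, subunits of complex I, with -1.58 ± 0.12 and -1.55 ± 0.12 (SE, n = 5 per group). All 76 measured ribosomal protein genes fell, with a median log2 fold change of -1.37. RPS9 fell from 1009 ± 243 to 276 ± 14.4 CPM and Rps23 from 1135 ± 235 to 366 ± 17.2 CPM. Both lists passed camera with the preset correlation (adjusted p = 6.07e-08 and 2.34e-18), and for both adjusted p = 0.922 with an estimated correlation. Both also varied among the untreated eyes. Relative to the control mean, the mean of the ribosomal genes was 0.32, 0.30, 0.04, -0.21 and -0.45 on the log2 scale in control libraries 1 to 5 and -1.53 to -1.23 in myopia. That of the respiratory chain was 0.09, 0.10, 0.17, -0.12 and -0.23 in control and -0.95 to -0.66 in myopia.

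Cell cycle genes fell in 17 of 30 cases and rose in 4, with a median log2 fold change of -0.58. BIRC5 (survivin) fell from 12.7 ± 2.16 to 3.50 ± 0.418 CPM, and the replication helicase genes MCM5 and MCM2 and the cell cycle inhibitor Cdkn1a fell with log2 fold changes of -0.76 ± 0.10, -0.83 ± 0.11 and -1.13 ± 0.11 (SE, n = 5 per group). The list passed camera with the preset correlation (adjusted p = 0.048; adjusted p = 0.922 with an estimated correlation). The call ended without control 1, control 2, control 5, myopia 1 or myopia 2, with adjusted p values of 0.0511, 0.0617, 0.0836, 0.0952 and 0.0613 and medians of -0.48, -0.54, -0.61, -0.52 and -0.47. Without control libraries 4 and 5 together the adjusted p was 0.1. Of 29 integrin and focal adhesion genes 18 rose and 9 fell. The integrin chains ITGB8, ITGA2 and ITGAV rose by 4.45 ± 0.35, 3.19 ± 0.28 and 0.96 ± 0.08, and the collagen receptor DDR2 by 1.45 ± 0.12. That list did not pass camera (adjusted p = 0.202).

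Interferon response genes were lower in the myopic sclera, 18 of 24 having fallen and 1 having risen, with a median log2 fold change of -1.35. Bst2 (tetherin) fell from 2126 ± 774 to 395 ± 128 CPM, and IFI35 and the immunoproteasome subunits PSMB9 and PSMB8 fell with log2 fold changes of -2.03 ± 0.16, -1.63 ± 0.17 and -1.42 ± 0.14 (SE, n = 5 per group). The list passed camera with the preset correlation (adjusted p = 0.000883; adjusted p = 0.922 with an estimated correlation). The mean of its members was 0.38, 0.19, -0.49, 0.11 and -0.19 in control libraries 1 to 5, relative to the control mean, and -1.63 to -0.60 in myopia. Of 21 macrophage and dendritic cell markers 11 fell and 1 rose, with a median log2 fold change of -0.79. CD14, SPI1, FCER1G and LAPTM5 fell with log2 fold changes of -1.76 ± 0.12, -1.98 ± 0.19, -1.70 ± 0.17 and -1.43 ± 0.15. PTPRC (CD45), carried by all white blood cells and named after its value was seen, rose by 1.25 ± 0.19. This list passed camera with the preset correlation (adjusted p = 0.048; adjusted p = 0.922 with an estimated correlation). The call ended without control 2, control 5, myopia 2, myopia 4 or myopia 5, with adjusted p values of 0.0594, 0.0765, 0.0544, 0.0647 and 0.0767 and medians of -0.70, -0.83, -0.73, -0.78 and -0.76. Without control libraries 4 and 5 together the adjusted p was 0.0654.

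Transcripts of red blood cells showed the strongest fall of the 38 lists. All 4 measured members were lower, with a median log2 fold change of -4.56. They were too few for the list test. The globins HBB and HBA fell from 3263 ± 1729 to 131 ± 66.0 CPM and from 2951 ± 1443 to 109 ± 67.2 CPM. ALAS2, the first enzyme of haem synthesis in red cells, fell from 34.0 ± 18.9 to 1.53 ± 1.03 CPM, and the membrane anion exchanger SLC4A1 from 2.96 ± 1.92 to 0.271 ± 0.0861 CPM. Skeletal muscle markers, included because eye muscles insert into the sclera, split: 11 of 40 fell, 3 rose and 26 did not pass (6 and 3 adjusted over the list alone). The troponin gene TNNT1 fell from 248 ± 66.9 to 107 ± 14.3 CPM. The very large sarcomere genes Ttn, NEB and Xirp2 rose by 2.07 ± 0.37, 2.28 ± 0.33 and 3.92 ± 0.64 on the log2 scale (SE, n = 5 per group). Xirp2 stood near the floor in control (0.957 ± 0.952 CPM). RYR1, also a large gene of this list and named after its value was seen, did not pass (0.003 ± 0.253, adjusted p = 0.993). The muscle list did not pass camera (adjusted p = 0.351). Inner retina and glia markers moved in 6 of 19 cases, 4 up and 2 down (3 and 2 adjusted over the list alone). The glial glutamate transporter SLC1A3 and water channel AQP4 rose by 1.36 ± 0.19 and 2.11 ± 0.36, and Prkca rose by 0.85 ± 0.14. THY1 fell by 1.07 ± 0.16, from 1712 ± 380 to 814 ± 113 CPM (mean ± SD). It also stands in the fibroblast identity list, so its fall cannot be assigned to retina. The list did not pass camera (adjusted p = 0.99).

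**Figure D2:**
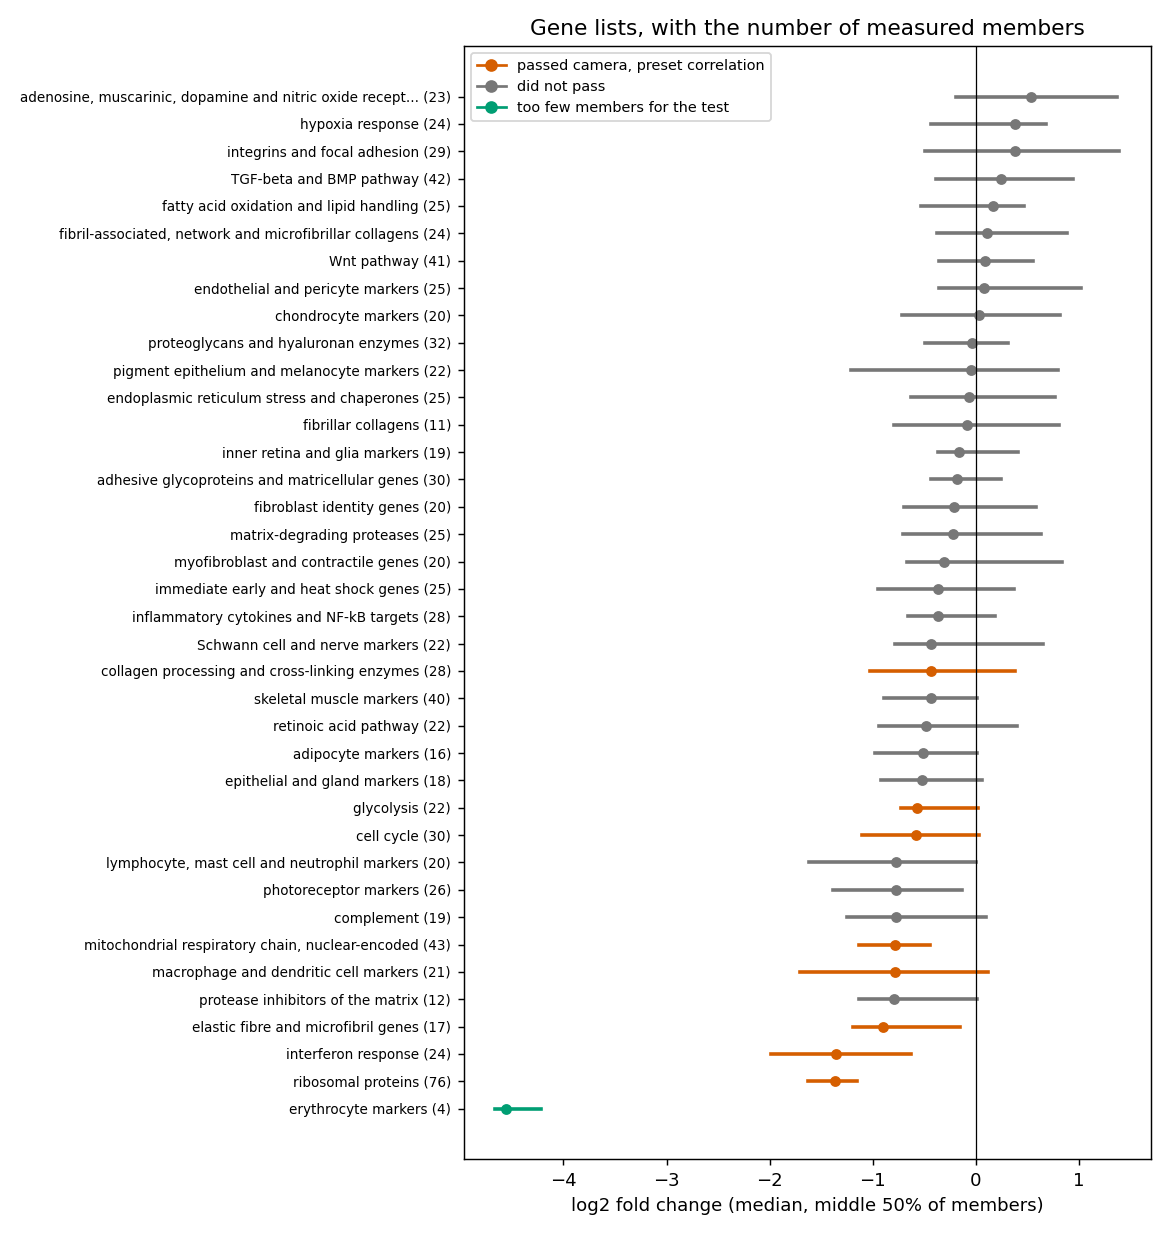
Median (point) and interquartile range over the measured members (bar) of the log2 fold change of each gene list, myopia against control, on the x axis, with the number of measured members after each name. Colour shows whether the list passed camera with the preset correlation, and the 8 lists that did lie below 0, with medians from -1.37 for ribosomal proteins to -0.43 for collagen processing enzymes, the last of which was 0.03 with scaling by total count. With an estimated correlation 0 lists passed camera (lowest adjusted p 0.922).

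The remaining lists did not pass camera, and their members are summarised by count. Of 30 adhesive and matricellular genes 5 rose and 10 fell (4 and 10 adjusted over the list alone; camera adjusted p = 0.404). The numbers that rose and fell, with the adjusted p of camera, were 12 and 10 of 41 Wnt pathway genes (0.99) and 5 and 11 of 22 retinoic acid genes (0.215). They were 12 and 5 of 23 receptors and synthases for adenosine, muscarinic, dopamine and nitric oxide signals with growth factors (0.355), and 10 and 10 of 25 lipid genes (0.95). For myofibroblast genes they were 6 and 9 of 20 (0.676), and for fibroblast identity genes 7 and 9 of 20 (0.578). For chaperones of the endoplasmic reticulum they were 10 and 9 of 25 (0.96). Of 25 immediate early and heat shock genes 5 rose and 11 fell (0.306), and of 28 cytokines and NF-kB targets 6 rose and 13 fell (0.355). Complement genes fell in 11 and rose in 2 of 19 cases (0.167). Lymphocyte, mast cell and neutrophil markers fell in 10 and rose in 1 of 20 (9 and 0 adjusted over the list alone; 0.193). Acta2, the myofibroblast actin, had a log2 fold change of -0.28 ± 0.19 that did not pass (adjusted p = 0.217). It was 0.18 with scaling by total count, and passed only without myopia 5 among the settings run (-0.44, adjusted p = 0.0469).

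Markers of neighbouring tissues gave 3 up and 10 down of 26 for photoreceptors (3 and 9 adjusted over the list alone; camera adjusted p = 0.12) and 6 and 8 of 22 for pigment epithelium and melanocytes (0.947). They gave 9 and 7 of 25 for endothelium and pericytes (0.848), and 2 and 7 of 18 for epithelium and glands (2 and 5 adjusted over the list alone; 0.306). They gave 6 and 6 of 20 for cartilage (0.947), 6 and 11 of 22 for Schwann cells and nerve (0.451), and 0 and 8 of 16 for fat (0 and 5 adjusted over the list alone; 0.256). The photoreceptor list passed without myopia 3 (median -1.11, adjusted p = 0.0307), without myopia 5 (median -1.16, adjusted p = 0.0153) and with scaling by total count (median -0.34, adjusted p = 0.00888), against a median of -0.78 with all libraries. Its fall was carried by myopia 1, 2 and 4, with means of the members of -1.51, -1.53 and -1.63 relative to the control mean. Myopia 3 and 5, at -0.04 and 0.23, lay within the control range of -0.24 to 0.45. Complement (adjusted p = 0.0278) and lymphocyte, mast cell and neutrophil markers (adjusted p = 0.0247) also passed with scaling by total count. In the other 29 of the 38 lists the counts adjusted over the list alone equalled those over all genes. The median, mean and camera direction differed in sign in 8 lists that did not pass: fibrillar collagens, proteoglycans, lipid genes, myofibroblast genes, chaperones, inner retina, cartilage and Schwann cells. With scaling by total count, 14 list medians turned from negative to positive, among them that of collagen processing enzymes, while those of the other 7 lists that passed came nearer to 0. These were -0.90 for ribosomal proteins, -0.90 for interferon response, -0.44 for elastic fibre genes, -0.33 for the respiratory chain, -0.33 for macrophage markers, -0.12 for glycolysis and -0.11 for cell cycle genes.

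The 10 genes with the highest fold changes were near the floor in control. ZBTB41, a zinc finger gene, went from 0.087 ± 0.0773 to 6.83 ± 0.953 CPM (13 and 1312 counts over 5 libraries), a log2 fold change of 6.20 ± 0.41 (SE; adjusted p = 1.47e-07). MDM4, an inhibitor of p53, went from 0.900 ± 0.878 to 29.7 ± 6.07 CPM, and ATP7A, a copper transporter, from 0.419 ± 0.484 to 13.4 ± 2.48 CPM. KAT6A, a histone acetyltransferase, went from 0.302 ± 0.349 to 9.61 ± 2.00 CPM, and SCN9A, a sodium channel, from 0.202 ± 0.161 to 6.18 ± 1.94 CPM. The others were ACADSB, an acyl-CoA dehydrogenase, Lmbrd2, Zbed6, GVINP1 and the second entry of PIK3C2A, with log2 fold changes from 4.98 to 5.95. All 10 rises shrank with the control axis projected out of the difference in mean log2 CPM. They went from 5.39 to 1.75 for KAT6A, from 6.01 to 2.22 for ACADSB, from 5.72 to 4.30 for ZBTB41 and from 4.78 to 3.78 for SCN9A. That step also takes out any response to the lenses along the axis. The 10 with the lowest fold changes held HBA, HBB and ALAS2, and Syt8, a synaptotagmin, which fell from 5.59 ± 1.16 to 0.051 ± 0.0629 CPM (808 and 10 counts), a log2 fold change of -6.65 ± 0.50 (adjusted p = 3.30e-07). SLC5A2, a sodium-glucose transporter, fell from 9.92 ± 1.27 to 0.762 ± 0.243 CPM, and IL12RB2, an interleukin receptor chain, from 5.94 ± 1.82 to 0.249 ± 0.148 CPM. Doc2a, ZACN, Nlrc3 and the second entry of LGALS9 had log2 fold changes from -5.19 to -4.67. PIK3C2A, LGALS9, Nlrc3, GVINP1, Zbed6, COL4A2, ECM2 and Xirp2 stand on more than 1 line of the table, and the globins belong to families of similar copies, so their reads may have been divided or shared and their values are uncertain.

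**Figure D3:**
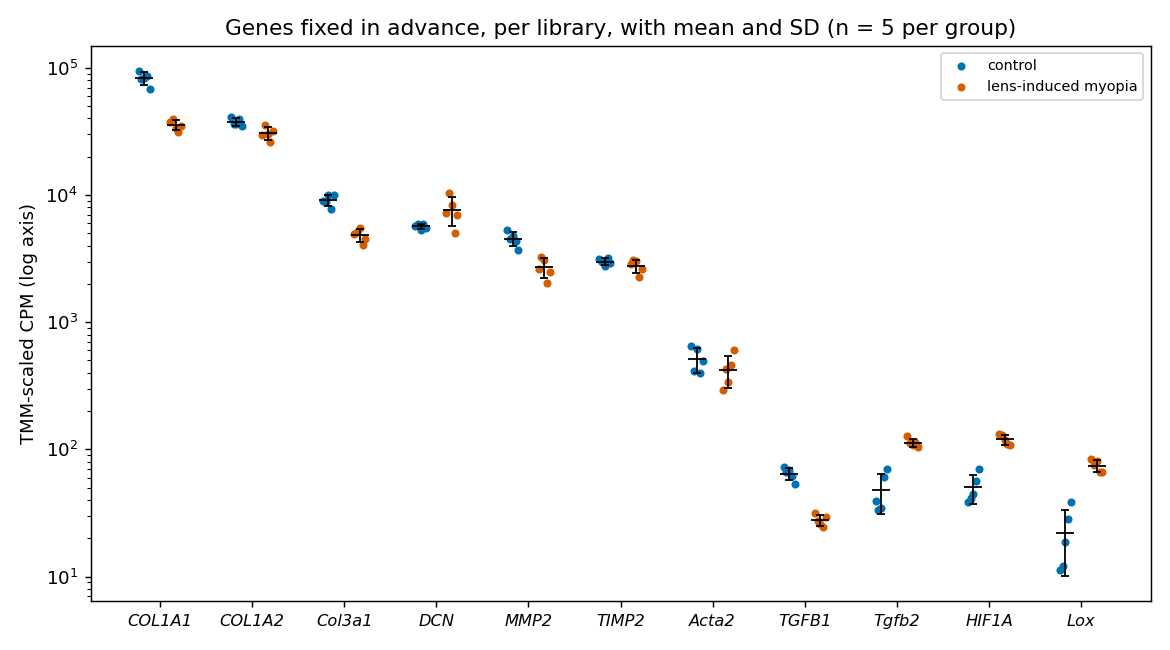
TMM-scaled CPM (log axis) of the 11 genes fixed in advance (x axis), with 1 point per library, and the mean and SD of the 5 libraries of each group in black. COL1A1 libraries lie between 31353 and 39733 CPM in myopia, below the 68637 to 94211 CPM of control, while COL1A2, TIMP2, Acta2 and DCN overlap between the groups; COL1A2, TIMP2 and Acta2 turn from lower to higher with scaling by total count.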

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

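Of the tests in this part, those of the library axis, transcript length and muscle were chosen after the result was seen, and the count of splits before. In 101 named genes and 5 measures per library, 212 groups of 5 values were examined, and in 14 of them a library lay apart from its nearest neighbour by more than 0.71 of the range. For independent, normally spread values chance sets apart about 1 in 20 such groups, here 10.6. These genes vary together and some values lie near the floor, so the 14 cannot be weighed against that number. Control 5 was the library set apart in 7 of the 14, and in each of these its value lay on the side of the myopia libraries. It stood at 1.70 CPM for Zbed6 (other controls 0.176 to 0.591), 1.45 for the second entry of PIK3C2A (0 to 0.295), 1.19 for ACADSB (0 to 0.131), 0.578 for Lmbrd2 (0 to 0.0789), 2.83 for Col4a3 (1.18 to 1.54) and 125.9 for ITGAV (114.8 to 118.0), and below the others at 5.01 for Doc2a (6.23 to 6.73). Among the myopia libraries, myopia 1 stood at 146.1 CPM for BMPR2 (103.3 to 108.5) and 269.0 for ITGAV (213.0 to 223.9), myopia 5 at 604.5 for ELN (459.0 to 500.9) and 8.82 for MCM2 (10.4 to 10.7), myopia 3 at 32.5 for HMOX1 (18.8 to 22.2), myopia 2 at 41.3 for IFI35 (29.5 to 31.3) and myopia 4 at 250.9 for RPS9 (277.1 to 287.3).

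Lines of the table without a gene symbol, which entered no comparison, also differed between the groups. Of 154 such lines with a mean of at least 1 CPM, 39 had all 5 myopia libraries above all 5 control libraries and 38 had them below. The most abundant fell from 6710 ± 2293 CPM in control to 885 ± 238 CPM in myopia (mean ± SD, n = 5).

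Among 100 splits of the 10 libraries into 5 and 5, only the real one called as many genes (10561). The highest of the others called 38. Since other splits mix the groups, the group difference widens the spread within them, and 38 does not measure chance. The splits also treat each eye as independent, which the labels do not show. They argue against a chance division of these 10 libraries only, not against the other sources of the difference weighed below. A changed share of muscle in the dissected tissue is argued against for 3 of the 5 myopia libraries only. In these, myopia 3, 4 and 2, the mean of the 40 muscle markers lay within the control range (-0.05, 0.09 and 0.40 against -0.39 to 0.56, relative to the control mean). Their median lay within its control range too. Myopia 1 and 5, at -0.50 and -1.37, lay below that of the mean, so less muscle is not excluded there. All 5 myopia libraries stood apart from control on the first principal component. The markers moved both ways, and the bound of 3 libraries was written after the result. A library axis that also runs through the untreated eyes stays open: its gene weights, from the 5 control libraries alone, correlated with the fold change at a Spearman rho of 0.73, and 52.3% of the squared difference between the groups lay along it, where the control libraries scored -39.4, -23.2, -15.8, 23.4 and 55 and the myopia libraries 91.4 to 104. The main axis of the 5 myopia libraries, with 37.7% of their variance, correlated with the fold change at -0.0113 and held 0.0301% of the squared difference. Genes vary together within libraries, so how often chance gives such a rho from 5 libraries is not known. Transcript length, as in RNA of differing integrity or libraries of differing fragment coverage, stays open as a source of the group difference. A share of 0.909 of the called genes with very large coding sequences, a list chosen after the data were seen, was higher. All 76 ribosomal protein genes, which are short, were lower. Whether the weights of the control axis follow length was not tested. With that axis projected out, the large genes Ttn, NEB and Xirp2 went from 2.02, 2.26 and 4.31 to 1.62, 1.65 and 0.72 on the log2 scale. Lengths and GC content were not analysed here, and a response of the sclera to lens wear, which the design names, stays open alongside.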

How the results depend on the processing

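The number of genes that differed (10561) lay between 10103 and 11180 under every other full-sample fit of the alternatives fixed beforehand, and between 10133 and 10854 when each library was left out in turn. The share that was lower did depend on the scaling: total count alone left 2751 lower genes of 10384, since it moves all fold changes up. The genes called also changed. Of the 10561 genes, 8223 were called with total count as well, against 10442 with RLE factors. With total count TIMP2 turned from -0.12 to 0.33 on the log2 scale (adjusted p = 0.00819). Leaving out a library gave 5229 to 5678 higher, 4879 to 5176 lower and 4409 to 5277 genes with an absolute log2 fold change of at least 1. The lists were less stable. Against 8 lists with the preset correlation, 5 passed with RLE factors, 5 with the filter of at least 1 CPM in 5 libraries and 5 with 1 surrogate variable; of the alternatives chosen after the data were seen, summing lines by symbol and leaving out control libraries 4 and 5 also gave 5 each. The lists lost were in each case collagen processing, cell cycle and macrophage markers, whose adjusted p lay near the threshold. An estimated correlation left 0 lists (lowest adjusted p 0.922), fry gave 16, total count gave 11, and leaving out a library gave 6 to 9. Besides the 8 lists, fry called hypoxia genes, integrins, and the list of receptors and synthases higher. It called protease inhibitors, retinoic acid genes, complement, cytokines and NF-kB targets, and adhesive and matricellular genes lower. The estimated correlations lay above the preset 0.01 in the 8 lists. They were 0.948 for ribosomal proteins, 0.669 for interferon response, 0.611 for the respiratory chain and 0.295 for macrophage markers. For elastic fibre, cell cycle, collagen processing and glycolysis genes they were 0.21, 0.193, 0.163 and 0.0436. The preset treats members as nearly independent, so its adjusted p values can be far too small for such lists. With 5 libraries per group the estimate of a correlation is itself uncertain. The shared numbers 1 to 5 do not pair the libraries: same-numbered libraries had correlations of -0.13 to 0.01 of their deviations and 0 of 5 control libraries correlated best with their own number. A replicate block on these numbers gave 10103 genes and 6 lists, without the calls for collagen processing, cell cycle and DCN (0.38, adjusted p = 0.0704). Among single genes and lists, 4653 values under the alternatives kept their side of the threshold (32 of them, 30 list medians and 2 genes, with the opposite sign, 16 of these with total count), 48 lost their call, 19 gained one, and 1, TIMP2 with total count, changed sign and passed only then. Genes near the floor in a group have fold changes that rest on few counts.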

Other observations

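Further gene groups were chosen, with their members, after the data were seen, and no group was tested as a whole. Of 28 splicing factor and nuclear speckle genes 26 rose and 0 fell, with a median log2 fold change of 1.09, among them Pnisr (2.09 ± 0.09 SE), TIA1 (1.70 ± 0.09) and DDX17, which went from 299 ± 21.1 to 814 ± 57.4 CPM (mean ± SD, n = 5). Of 258 genes whose symbols begin with ZNF, most of them zinc finger genes, 150 rose and 53 fell (median 0.64). Of 18 circadian clock genes 8 rose and 6 fell: CLOCK rose from 4.40 ± 1.55 to 28.9 ± 2.45 CPM and NR1D2 from 63.9 ± 4.15 to 219 ± 15.2 CPM, while Nr1d1 fell from 67.7 ± 21.1 to 37.9 ± 1.99 CPM and CRY2 from 68.9 ± 5.23 to 41.7 ± 2.95 CPM. Times of sampling are not given in the sources used here. Of 77 genes with very large coding sequences, 50 rose and 5 fell (median 0.87); ATM rose by 2.95, DMD by 3.84 and BRCA2 by 3.15 on the log2 scale, and those that fell were Plec, AHNAK, Dchs1, DYNC1H1 and COL6A3, with log2 fold changes of -0.30, -0.41, -0.42, -0.49 and -0.47.

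Transcripts of tissues next to the sclera were present in both groups. Of 10 lens fibre genes 9 fell, with a median log2 fold change of -1.90, including BFSP2, which fell from 36.7 ± 11.2 to 13.0 ± 2.56 CPM, and Cryaa, from 14.5 ± 11.6 to 2.10 ± 2.66 CPM (mean ± SD, n = 5). GFAP, the astrocyte filament, stood at 2590 ± 481 CPM in control and 1716 ± 883 CPM in myopia, and Mbp, a myelin protein, at 2532 ± 753 and 2041 ± 976 CPM; neither passed the test (adjusted p = 0.131 and 0.426). Of 15 markers of optic nerve glia 3 rose and 4 fell (median -0.26).

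With the axis of the control libraries projected out of the group difference, a step chosen after the data were seen and carrying no test, list medians on the log2 scale moved from -1.34 to -0.52 for ribosomal proteins, from -0.78 to -0.36 for the respiratory chain, from -0.90 to -0.66 for elastic fibre genes, from -0.57 to -0.49 for glycolysis, from -0.44 to -0.29 for collagen processing, from -0.55 to -0.32 for cell cycle genes, from -0.78 to -0.67 for macrophage markers and from 0.41 to 0.07 for hypoxia genes. Medians of 29 lists came nearer to 0 and those of 9 moved farther from it, among them photoreceptor markers (-1.18 to -1.50, where the fall rests on 3 of the 5 myopia libraries), immediate early and heat shock genes (-0.32 to -0.62), proteoglycans (-0.05 to -0.35) and Wnt pathway genes (0.08 to -0.32). The starting values here are differences in mean log2 CPM with a prior count of 2. They can therefore differ from the edgeR medians given above, which was -0.78 for photoreceptor markers. Lox, Tgfb2 and HIF1A went from 1.92, 1.31 and 1.29 to 0.02, 0.17 and 0.37. Col3a1 went from -0.92 to -0.95, ELN from -1.43 to -1.41 and IL33 from 2.06 to 1.66. The step takes out any response to the lenses along the axis as well, so the values left are not corrected effects.

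The tests on globin and interferon genes, of blood, of macrophages and with the control axis, were chosen after the data were seen, and only the bounds of those with the control axis were written before their values. HBA, HBB and ALAS2 were lower in all 5 myopia libraries than in all 5 control libraries. The library axis is argued against as their source: with it projected out, their mean log2 fold change was still -4.19. Less blood in the myopia samples stays open as a candidate explanation. The 4 measured red cell markers all fell, but their log2 fold changes spread over 1.32, between the bounds of 1 and 2 set for this test, since SLC4A1, with few counts in myopia, fell by less. Whether blood differed through dissection and rinsing or through the vessels of the treated eyes was not tested.

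For the lower interferon genes, fewer macrophages stay open. The SD of the log2 fold changes of 21 macrophage and dendritic cell markers was 1.17, with PTPRC higher by 1.25 ± 0.19, MRC1 at 0.26 ± 0.23 and CD14 lower by 1.76 ± 0.12 on the log2 scale. It was 0.923 with the control axis projected out, under the bound of 1, so the markers do not exclude a lower share of these cells. With the control axis projected out the list's median was -0.88 (95% bootstrap interval -1.33 to -0.49), with 21 of 24 members below 0. The bootstrap resampled the 24 genes, not the libraries. These genes vary together (estimated correlation 0.669), so the interval does not measure the spread between libraries or animals. The median itself lay below the bound of -0.7 written beforehand, which by that bound alone argues against the axis as the only source of the fall. A further condition, that the whole interval lie below -0.7, was not part of that bound and was not met. Since the interval does not measure the spread between libraries, it cannot decide how much of the fall the axis accounts for. A part played by the axis, fewer macrophages and a lower interferon signal in the treated sclera cannot be told apart for these genes, and all stay open.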
